A study of Mus musculus with 14 samples.

How the data were processed

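RNA of pancreatic islets from 14 mice, each sample from a separate mouse by the wording of the labels, was measured on a whole-transcript expression array. Per the labels, islets were snap-frozen, RNA was extracted with Trizol and a column kit with DNase, and 100 ng of total RNA was labelled with biotin. The deposited values are log2 signals that the authors made by RMA (background correction, normalization and probe set summary), per the submitters' processing notes, whose version is not given in the sources used here. The table holds 35556 probe sets. Of these, 21218 carried exactly 1 gene symbol, 1881 carried several and 12457 none, and the latter kinds were left out of the gene tests. Symbols were matched by Entrez identifier for 18790 genes, and 30 kept the platform's symbol. Where a gene had several probe sets, as 1386 did, the brightest over all arrays was used, which gave 18820 genes. Ins1 has no probe set with a single symbol and was not analysed here. All table columns were matched to samples. The values were used as deposited, without further normalization.

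Groups follow genotype and time on the diet: WT at 5 weeks (4 arrays), DKO at 5 weeks (2), WT at 7 months (4) and DKO at 7 months (4). A linear model with 1 mean per group was fitted to all 14 arrays with limma 3.58.1 (lmFit and eBayes with the default prior) in R 4.3.3. The 5 comparisons were DKO against WT at each time, 7 months against 5 weeks in each genotype, and the interaction. P-values were adjusted by Benjamini-Hochberg within each comparison and judged at 0.05 with no minimum fold change. They measure the spread between these samples. Differences are given with the SE of the model, and for the targeted genes an exact permutation test of the group labels was added. Gene lists were written down for signalling, cell cycle, metabolism and cell types, 31 in all, of which 30 had at least 3 measured genes, the red blood cell list being left out. Of 524 genes named in the lists 464 were measured. Lists were tested with limma's camera at its preset correlation of 0.01, adjusted over the 30 lists, and again with the correlation estimated for each list. A list is called shifted when its camera adjusted p passed at the preset correlation. A score of acinar RNA was the mean of the acinar genes per array, each centred over the arrays. Figures and tables were made with Python 3.11.15 and matplotlib 3.10.9.

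Genes are named by a rule: Tlr2 and Tlr4, the 10 largest rises and the 10 largest falls past the threshold in each comparison, up to 4 members of each list with the smallest p, and in each comparison Ins2, Gcg, Sst, Mki67 and Ccnd2. Placeholder symbols and large repeat families were passed over, and where under 5 genes passed in a direction those of smallest p were to be named as not passed. The comparisons, the tests, the threshold and the alternatives were fixed before the data were examined. The alternatives were to fit only the arrays compared, to use a trended robust prior, to leave out dim genes, to average the probe sets of a gene, to repeat quantile normalization, to centre each array on its median, to test all probe sets, to add the replicate number, the number 5 or 7 in the description labels or the acinar score to the model, to weight arrays, to estimate the correlation in camera, and to leave out each array in turn. With an array of DKO at 5 weeks left out, the lone array was assumed to vary like the other groups. The letters in the description labels run with the groups, so an effect of what they stand for is not separable from the group.

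The method was tested on simulated data with the group sizes of this series, 18820 genes and 50 changed genes at each fold change. At 1.5-fold it recovered 40% at 5 weeks and 66% at 7 months for genotype, 44% in WT and 42% in DKO for time, and 12% for the interaction. At 2-fold it recovered 84%, 88%, 96%, 88% and 62%, at 3-fold 98%, 100%, 100%, 98% and 96%, and at 4-fold 96%, 100%, 98%, 100% and 96%. Of its calls, 5.36%, 4.84%, 3.98% and 4.65% were false in the comparisons other than the interaction. The simulated noise was drawn separately for each gene, with no correlation between genes and no shift of a whole array. These rates therefore need not hold for the real arrays. A fold change under 2 could thus be missed, most of all in the interaction. The median SE of a gene's log2 difference in the data was 0.14 at 5 weeks and 0.11 at 7 months. Array medians lay between 3.89 and 3.98. Pairs of arrays correlated at 0.986 to 0.995 within groups and 0.978 to 0.993 between groups.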

Results

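Pancreatic islets of 14 mice fed a high-fat diet were profiled on a whole-transcript expression array, with 1 array per sample. The mice were wild-type C57BL/6 (WT) or lacked both Toll-like receptor 2 and Toll-like receptor 4 (DKO), innate immune receptors for bacterial lipopeptides and lipopolysaccharide. The diet, with 60% fat, began at 6 weeks of age and lasted 5 weeks (4 WT and 2 DKO arrays) or 7 months (4 WT and 4 DKO arrays). The series title concerns the role of these receptors in beta cell expansion in obesity, which frames the comparison of genotypes at each time and of times within each genotype. Mice were older at the later time, so time on the diet and age were not separable. The deposited table holds log2 RMA values of 35556 probe sets, and 18820 genes were tested. Array medians lay between 3.89 and 3.98 on the log2 scale. The number of arrays limits the precision.

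The targeted genes were examined first. Tlr2 (probe set 10498992) was 4.79 ± 0.03 (SD, n = 2) in DKO and 6.45 ± 0.17 (n = 4) in WT islets at 5 weeks, and 5.31 ± 0.10 (n = 4) against 6.37 ± 0.14 (n = 4) at 7 months. It fell by 1.66 ± 0.12 (SE) on the log2 scale at 5 weeks (limma adjusted p = 9.71e-06) and by 1.06 ± 0.10 at 7 months (adjusted p = 1.61e-05), and each DKO array lay below each WT array. The two-sided exact permutation p was 0.0667 at 5 weeks and 0.0286 at 7 months, in each case the lowest that the number of arrays allows. Tlr4 (probe set 10505517) was dimmer, at percentile 38 of the probe sets and 2.86 to 3.30 in the group means, and did not pass the test at 5 weeks (0.35 ± 0.20, limma adjusted p = 0.506, exact permutation p = 0.0667) or 7 months (0.31 ± 0.16, adjusted p = 0.331, exact permutation p = 0.286). At 5 weeks both DKO arrays (3.19 and 3.23) lay above all WT arrays (2.79 to 2.90), against the direction of a knockout, and 0.0667 is again the lowest possible p. Whether either probe set lies in the deleted part is not given in the sources used here, so the Tlr4 values do not check the labels.

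**Figure D1:**
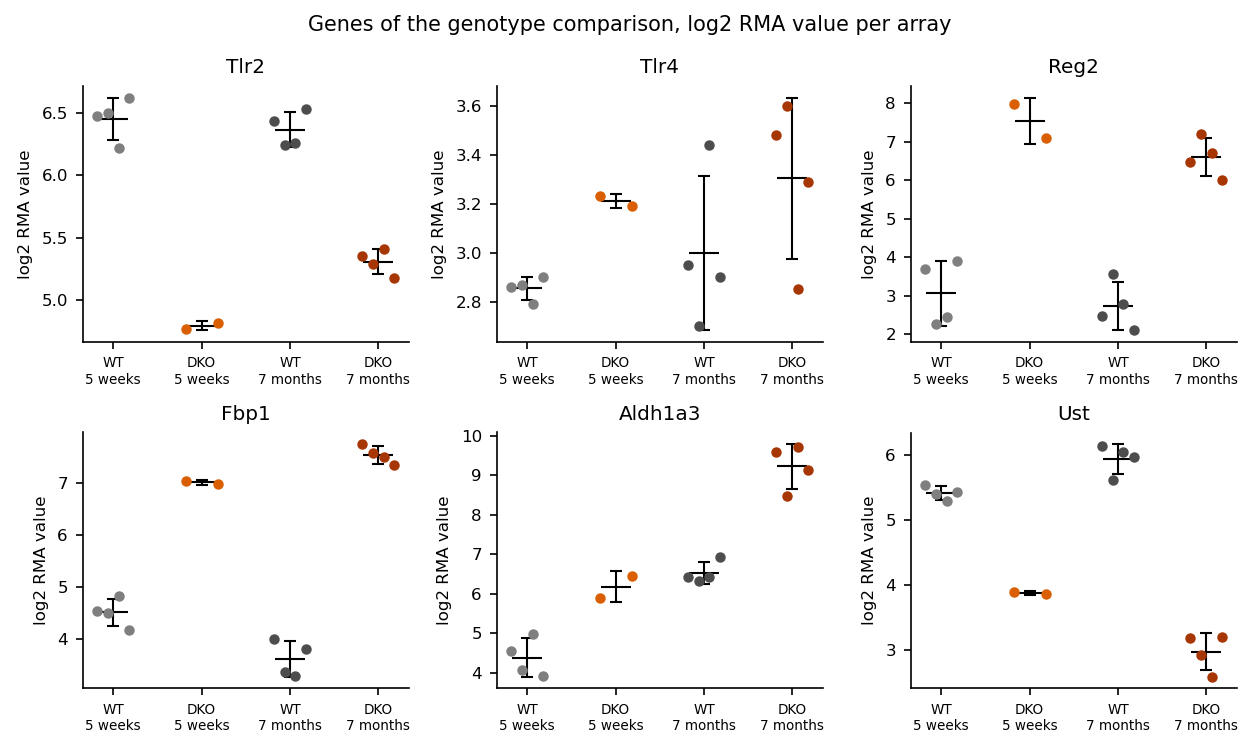
Log2 RMA value (vertical axis) of Tlr2, Tlr4, Reg2, Fbp1, Aldh1a3 and Ust in each array (points) of the 4 groups (horizontal axis), with the group mean (bar) and SD (whisker). Tlr2 reached at most 5.41 in DKO arrays and at least 6.22 in WT arrays, while Reg2 reached at most 3.89 in WT arrays and at least 6.01 in DKO arrays.

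At 5 weeks, Reg2, a secreted regenerating protein, rose in DKO islets by 4.47 ± 0.48 log2 units (SE; 22.2-fold, limma adjusted p = 0.000279, n = 2 and 4). Fbp1, a gluconeogenic bisphosphatase, rose 5.69-fold (2.51 ± 0.20, adjusted p = 1.81e-05), and Aldh1a3, a retinaldehyde dehydrogenase used as a marker of dedifferentiated beta cells, rose 3.47-fold (1.80 ± 0.33, adjusted p = 0.0174). Nnt, a mitochondrial transhydrogenase that supplies NADPH, rose by 1.53 ± 0.11 (adjusted p = 9.71e-06). The largest falls included Ndufs5, a subunit of respiratory complex I (-1.94 ± 0.16, adjusted p = 3.4e-05), Rec8, a meiotic cohesin subunit (-1.93 ± 0.22, adjusted p = 0.000468), and Npas4, an activity-dependent transcription factor (-1.72 ± 0.34, adjusted p = 0.0258). In all, 187 of 18820 genes passed, 94 higher and 93 lower, and 51 of them changed at least 2-fold. For 5 of the 22 named genes past the threshold (Npas4, Rec8, Reg2, Reg3b and Ust) the lower group mean lay below all array medians, so the sizes of their changes are not exact.

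Among the other large rises were Trnp1 (2.37 ± 0.23), Reg3b, another secreted Reg protein (1.94 ± 0.38), Fam163a (1.76 ± 0.36), Fam107a (1.71 ± 0.36), the non-coding RNA Snhg11 (1.60 ± 0.17) and Cyp39a1, an oxysterol hydroxylase (1.47 ± 0.24). Among the other large falls were Dock10 (-1.69 ± 0.21), Glt1d1 (-1.59 ± 0.15), Dio1, a thyroid hormone deiodinase (-1.55 ± 0.15), Ust, a uronyl sulfotransferase (-1.54 ± 0.17), Depp1 (-1.53 ± 0.27) and Pcp4l1 (-1.51 ± 0.26). The hormone genes Ins2, Gcg and Sst, the proliferation marker Mki67 and the cyclin gene Ccnd2 did not pass, with differences of 0.00 ± 0.09, -0.09 ± 0.11, -0.06 ± 0.10, -0.25 ± 0.67 and -0.02 ± 0.13. Mki67 was 3.52 in DKO replicate 1 and 6.22 in replicate 2, below and above all WT arrays (4.84 to 5.45). Means of the G2 and mitosis list split the same way (-0.436 and 0.678, against 0.041 to 0.183 in WT). These arrays thus do not settle whether proliferation genes differed at 5 weeks. The hormone genes had high signals with little spread at 5 weeks (Ins2 11.76 to 11.99, Gcg 12.81 to 13.01 and Sst 12.78 to 12.91). Whether their probe sets can show a rise at that level was not tested, nor whether that of Ins2 can show a fall. Those of Gcg and Sst did show falls, with means at 7 months of 12.09 in DKO against 12.78 in WT, and 11.74 against 12.62. Of the 22 named genes past the threshold, 12 stayed past it whichever array was left out, and Reg3b, Aldh1a3, Fam163a, Fam107a, Cyp39a1, Npas4, Depp1, Pcp4l1, Acadl and Acta2 did not. The count of 187 became 44 without DKO replicate 1, 104 without WT replicate 2 and 120 without WT replicate 1 of the 5-week arrays, 98 with the acinar score as a covariate, 120 with only the arrays compared and 282 with a trended robust prior.

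Of the 30 gene lists, 6 were shifted at 5 weeks by limma's camera test. In the Reg family 2 of 7 measured genes rose and 5 did not pass (4 higher adjusted over the list alone; camera adjusted p = 6.37e-05), and Reg3d, at 2.11 ± 0.51, had an adjusted p of 0.0701. For this list adjusted p = 0.4 with an estimated correlation. With the acinar score as a covariate Reg2 still passed and Reg3b, at 1.77 about as large as before, did not (limma adjusted p = 0.0944). Of 26 acinar genes, which encode digestive enzymes and their regulators, 0 passed (0 adjusted over the list alone), with a median of 1.14 and values of 2.27 ± 0.74 for Ctrc, a chymotrypsin, and 1.56 ± 0.59 for Gp2, a zymogen granule protein. That list was higher at camera adjusted p = 6.37e-05, with adjusted p = 0.919 with an estimated correlation. Its mean relative to all arrays was -1.50 in WT replicate 2 and 0.34 to 0.58 in the other WT arrays, against 1.28 and 0.77 in DKO. Of 22 interferon response genes 0 passed (3 higher and 1 lower adjusted over the list alone), with Irf7, a transcription factor of that response, at 0.96 ± 0.23, Usp18, an interferon-induced protease, at 0.47 ± 0.13 and Rsad2, an antiviral enzyme, at -0.85 ± 0.24. The list was higher at camera adjusted p = 0.00413, with adjusted p = 0.919 with an estimated correlation, and without DKO replicate 2 it had adjusted p = 0.485.

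Of 15 genes in the fatty acid oxidation and PPAR targets list 1 fell, Acadl, a long-chain acyl-CoA dehydrogenase (-0.87 ± 0.19, limma adjusted p = 0.0388), and 14 did not pass (2 lower adjusted over the list alone), with Acot2, a mitochondrial thioesterase, at -0.52 ± 0.12. Camera gave adjusted p = 0.0206 for it, with adjusted p = 0.314 with an estimated correlation, 0.0561 without WT replicate 1 and 0.103 without DKO replicate 2. Of 21 genes in the immediate early and tissue handling genes list 0 passed (3 lower adjusted over the list alone), with Nr4a1, an orphan nuclear receptor, at -1.49 ± 0.37 and Zfp36, which speeds mRNA decay, at -0.60 ± 0.14. Its camera adjusted p was 0.0206, with adjusted p = 0.919 with an estimated correlation, and it was 0.062 without WT replicate 3, 0.0555 without WT replicate 4 and 0.103 without DKO replicate 2. Of 23 genes in the beta cell list 0 passed (0 adjusted over the list alone), with Isl1 at -0.31 ± 0.16 and Mafa at 0.48 ± 0.22, both islet transcription factors. Its camera adjusted p was 0.0325, with adjusted p = 0.919 with an estimated correlation, and 0.0825 without WT replicate 2, 0.082 without WT replicate 4, 0.165 without DKO replicate 1 and 0.09 without DKO replicate 2. In the lists that were not shifted, Acta2, a smooth muscle actin in the stellate cell list, fell by 0.98 ± 0.17. Median, mean and test differed in sign for the lists of G2 and mitosis, G1 cyclins, disallowed genes, PP and epsilon, duct, B and plasma cells and adipocytes, none of which was shifted.

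At 7 months, Fbp1 and Reg2 rose in DKO against WT islets, and several hormone genes of non-beta endocrine cells fell. Fbp1 rose by 3.94 ± 0.16 (SE; 15.3-fold, limma adjusted p = 6.04e-09, n = 4 and 4), Reg2 by 3.87 ± 0.39 (14.6-fold, adjusted p = 4.05e-05) and Aldh1a3 by 2.69 ± 0.27 (6.47-fold, adjusted p = 3.9e-05). Ust fell by 2.97 ± 0.14 (adjusted p = 1.4e-08) and Ppargc1a, a coactivator of mitochondrial biogenesis, by 2.95 ± 0.25 (adjusted p = 6.87e-06). Pyy, which encodes peptide YY, fell by 1.40 ± 0.12 (adjusted p = 6.27e-06), the somatostatin gene Sst by 0.88 ± 0.08 (adjusted p = 2.35e-05) and the glucagon gene Gcg by 0.69 ± 0.09 (adjusted p = 0.000374). In all, 887 genes passed, 460 higher and 427 lower, 147 of them at least 2-fold. The sizes of change are not exact for 24 of the 61 named genes past the threshold, whose lower group mean lay below all array medians: Fbp1 (3.61 in WT), Reg2, Ust, Ppargc1a, Npas4, Msln, Mlph, Clmp, Cck, Prss3, Bcat1, Vnn1, Itih1, Reg3a, Reg3b, Reg3d, Irx1, Pdgfra, Fcgr1, Mrc1, Itgam, Vwf, Pdk4 and Cxcl2.

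The other large rises were Clmp, a cell adhesion protein (2.79 ± 0.32), Cck, the cholecystokinin gene (2.63 ± 0.54), Trnp1 (2.43 ± 0.18), the trypsinogen gene Prss3 (2.38 ± 0.58), Bcat1, a branched-chain aminotransferase (2.29 ± 0.29), Vnn1, a pantetheinase (2.07 ± 0.13), and Itih1 (2.01 ± 0.45). Cck was 2.96 in DKO replicate 2, near the WT mean of 2.77, and 6.01 to 6.54 in the other DKO arrays. The other large falls were Dpp10, a partner of potassium channels (-2.51 ± 0.18), Npas4 (-2.43 ± 0.28), mesothelin, Msln (-2.41 ± 0.24), Clip4 (-2.23 ± 0.15), Dock10 (-2.18 ± 0.17), Mlph, a melanosome transport protein (-2.05 ± 0.22), the potassium channel gene Kcng3 (-1.94 ± 0.34) and Rbp4, the retinol carrier (-1.91 ± 0.14). Of 61 named genes past the threshold 43 stayed past it whichever array was left out. The count of 887 became 528 without WT replicate 1 or without WT replicate 2, 531 without DKO replicate 3 and 1681 without DKO replicate 2 of the 7-month arrays, 488 with only the arrays compared and 586 with the acinar score as a covariate. With each array centred on its median, 674 genes were higher and 294 lower.

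Among the endocrine lists, 3 of 3 PP and epsilon cell genes fell (3 lower adjusted over the list alone), namely Pyy, the pancreatic polypeptide gene Ppy (-0.82 ± 0.17) and the ghrelin gene Ghrl (-1.40 ± 0.34). Camera gave adjusted p = 1.17e-05, and adjusted p = 0.0734 with an estimated correlation. Of 6 alpha cell genes 3 fell and 3 did not pass (3 lower adjusted over the list alone), namely Gcg and the transcription factors Irx1 (-0.71 ± 0.15) and Irx2 (-1.22 ± 0.13), while Ttr, encoding transthyretin, was at 0.21 ± 0.16. The list had camera adjusted p = 0.000842, and adjusted p = 0.0734 with an estimated correlation. Of 5 delta cell genes Sst and Rbp4 fell and 3 did not pass (1 higher and 3 lower adjusted over the list alone), with the leptin receptor gene Lepr at 0.56 ± 0.17. The list had camera adjusted p = 0.000783, and adjusted p = 0.0734 with an estimated correlation. Of 23 beta cell genes 0 passed (6 lower adjusted over the list alone), with the glucose transporter gene Slc2a2 at -0.64 ± 0.18, urocortin 3, Ucn3, at -0.37 ± 0.11, the zinc transporter gene Slc30a8 at -0.38 ± 0.11 and Isl1 at -0.45 ± 0.13. That list was lower at camera adjusted p = 0.000826, and adjusted p = 0.369 with an estimated correlation. Its mean in DKO replicate 2 (0.15) lay above all WT arrays (0.05 to 0.11), and those of the other 3 DKO arrays (-0.27 to -0.11) lay below them. Ins2 differed by 0.02 ± 0.07 and lay between 11.76 and 11.99 on the log2 scale in all 14 arrays. With so little spread at so high a signal, whether this probe set can show a change was not tested.

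**Figure D2:**
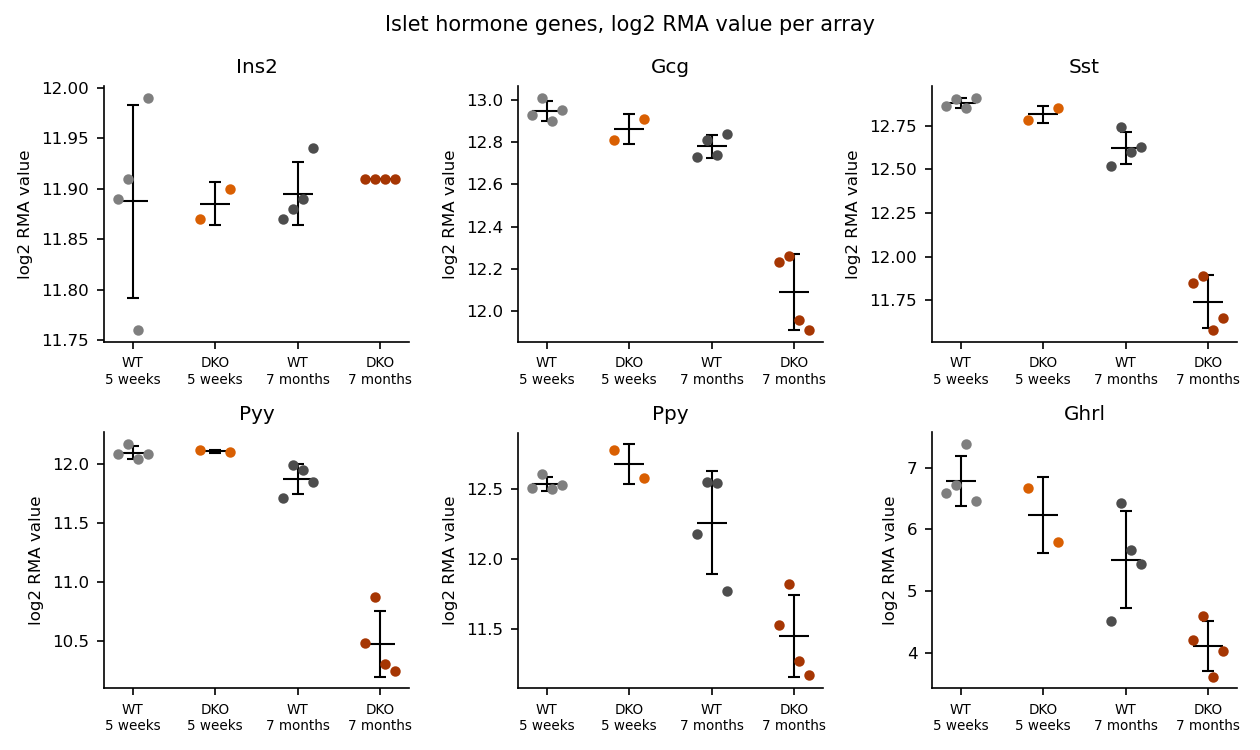
Log2 RMA value (vertical axis) of Ins2, Gcg, Sst, Pyy, Ppy and Ghrl in each array (points) of the 4 groups (horizontal axis), with the group mean (bar) and SD (whisker). Gcg averaged 12.09 in DKO and 12.78 in WT islets at 7 months, and Pyy 10.48 and 11.87, while Ins2 group means lay between 11.88 and 11.91, a spread too small to show whether the probe set responds.

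Of 15 genes in the stellate cell, pericyte and fibroblast list 8 rose and 7 did not pass (12 higher adjusted over the list alone), among them the proteoglycan gene Dcn (1.96 ± 0.30), the collagen genes Col3a1 (1.18 ± 0.18) and Col1a1 (0.97 ± 0.18), and Pdgfra, a growth factor receptor (0.83 ± 0.13). Camera gave adjusted p = 6.51e-10, and adjusted p = 0.118 with an estimated correlation. Over time, Dcn and Pdgfra fell in WT islets and did not pass in DKO islets, so their differences here partly reflect a fall in WT. Of 20 macrophage genes 4 rose and 16 did not pass (4 higher adjusted over the list alone), the Fc receptor gene Fcgr1 (0.62 ± 0.12), the lysozyme gene Lyz2 (0.96 ± 0.21), the mannose receptor gene Mrc1 (0.62 ± 0.15) and the integrin gene Itgam (0.55 ± 0.15). The macrophage list had camera adjusted p = 0.00116, adjusted p = 0.439 with an estimated correlation, and 0.0634 without DKO replicate 4. Of 13 T and NK cell genes and 11 B and plasma cell genes 0 passed (0 adjusted over either list alone). These lists were higher at camera adjusted p = 0.016 and 0.0242, with adjusted p = 0.536 for both with an estimated correlation. Without DKO replicate 4, whose T and NK cell mean lay 1.25 log2 units above the mean of all arrays, they had adjusted p = 0.656 and 0.593, and the B and plasma cell list had 0.0555 without WT replicate 1. Without DKO replicate 4 the count of shifted lists fell from 18 to 10.

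Of 16 endothelial cell genes, the receptor gene Tek (0.57 ± 0.09) and the clotting factor gene Vwf (0.82 ± 0.14) rose, Emcn, an endothelial sialomucin, fell by 0.36 ± 0.09, and 13 did not pass (3 higher and 1 lower adjusted over the list alone). The endothelial cell list had camera adjusted p = 0.038, adjusted p = 0.502 with an estimated correlation, and 0.0555, 0.112, 0.117 and 0.149 without WT replicate 1, WT replicate 2, DKO replicate 2 and DKO replicate 4. Of 26 acinar genes 1 rose, Prss3, and 25 did not pass (1 higher adjusted over the list alone). The acinar list was higher at camera adjusted p = 5.02e-05, with adjusted p = 0.502 with an estimated correlation, and the genotypes overlapped in it. Its mean relative to all arrays was -1.05, 0.67, -0.38 and -2.18 in WT replicates 1 to 4 and between 0.01 and 0.58 in the 4 DKO arrays. Of 8 duct genes 1 fell, the tetraspanin gene Tspan8 (-1.05 ± 0.21), and 7 did not pass (1 lower adjusted over the list alone), and the list had adjusted p = 0.472. The lists of Schwann cells (0 of 5 genes passed), adipocytes (0 of 8) and sex-linked genes (0 of 4) also had 0 genes adjusted over the list alone, and camera adjusted p of 0.639, 0.465 and 0.612.

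**Figure D3:**
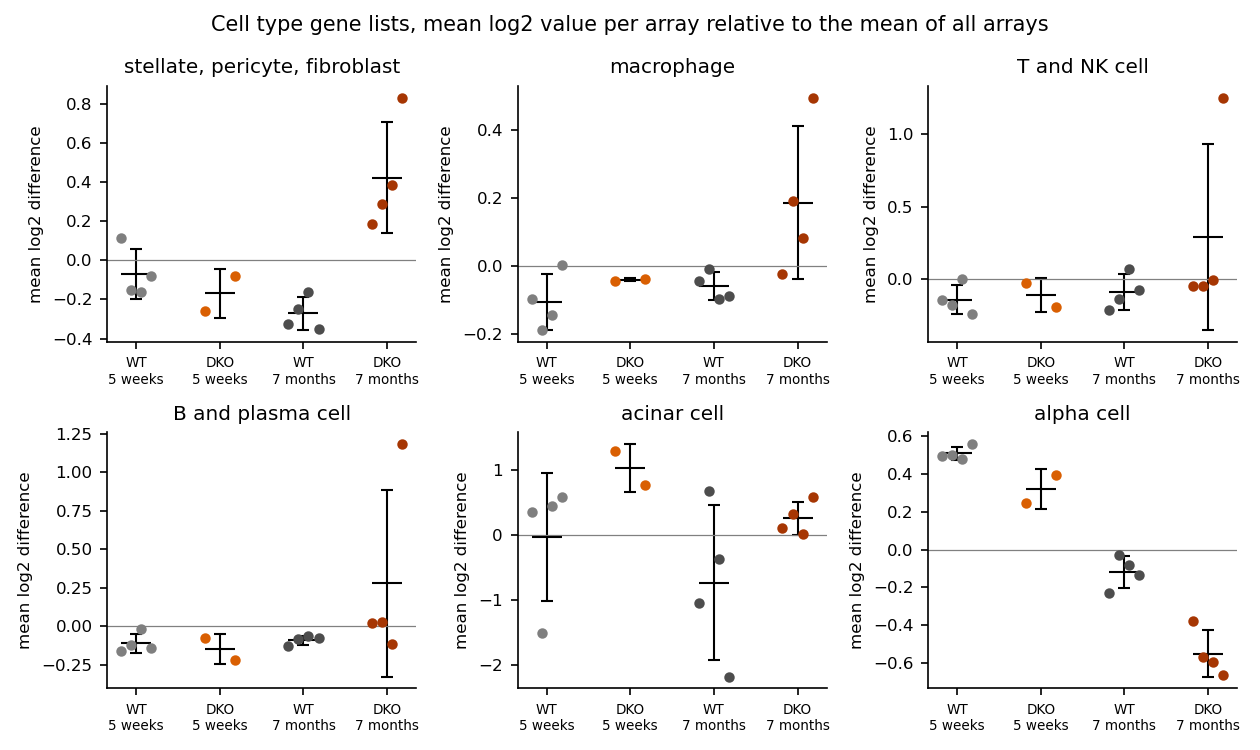
Mean log2 value of 6 cell type gene lists (vertical axis, relative to the mean of all arrays) in each array (points) of the 4 groups (horizontal axis), with the group mean (bar) and SD (whisker). DKO replicate 4 at 7 months stands at 1.25 for T and NK cell genes and 1.18 for B and plasma cell genes.

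In the Reg family 4 of 7 genes rose and 3 did not pass (5 higher adjusted over the list alone), including Reg3a (0.92 ± 0.17), Reg3b (1.35 ± 0.31) and Reg3d (1.74 ± 0.42) beside Reg2. The Reg family list had camera adjusted p = 5.64e-05, and adjusted p = 0.182 with an estimated correlation. The acinar list was higher in the same comparison, and among the WT arrays the lowest Reg family mean (-1.29) and the lowest acinar mean (-2.18) were both in replicate 4. With the acinar score as a covariate Reg2 and Reg3a still passed, while Reg3b (1.19, limma adjusted p = 0.089) and Reg3d (1.11, adjusted p = 0.0682) did not, though Reg3b stayed about as large. Of 21 unfolded protein response genes 3 rose and 18 did not pass (3 higher adjusted over the list alone). These were Sel1l (0.44 ± 0.10) and Edem1 (0.49 ± 0.12), which serve degradation of misfolded proteins, and the chaperone cofactor gene Dnajc3 (0.50 ± 0.13). That list had camera adjusted p = 5.64e-05, and adjusted p = 0.369 with an estimated correlation. Of 16 genes in the islet disallowed and dedifferentiation genes list, Aldh1a3, Cck and Igfbp4, a growth factor binding protein (1.12 ± 0.22), rose and 13 did not pass (3 higher adjusted over the list alone). It had camera adjusted p = 0.016, adjusted p = 0.369 with an estimated correlation, and 0.149 without DKO replicate 4. Of 32 oxidative phosphorylation genes Ndufa1 of complex I rose (0.43 ± 0.11), Sdhc of complex II fell (-0.29 ± 0.08), and 30 did not pass (3 higher and 1 lower adjusted over the list alone). The oxidative phosphorylation list had camera adjusted p = 0.0264, adjusted p = 0.431 with an estimated correlation, and 0.0961, 0.0584, 0.0601 and 0.0976 without WT replicate 2, WT replicate 3, DKO replicate 3 and DKO replicate 4. Of 15 fatty acid oxidation and PPAR target genes Pdk4, which inhibits pyruvate dehydrogenase, fell by 1.46 ± 0.12 and Acadl by 1.24 ± 0.15, and 13 did not pass (1 higher and 3 lower adjusted over the list alone), and the list had adjusted p = 0.0546. Of 15 cholesterol synthesis genes 0 passed (0 adjusted over the list alone), with list adjusted p = 0.28.

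Lists of the cell cycle differed in their members and tests. Of 24 S phase and DNA replication genes 0 passed (0 adjusted over the list alone), with E2f1, an activator of replication genes, at 0.60 ± 0.18. All 24 lay above 0, and that list had camera adjusted p = 0.000198, and adjusted p = 0.502 with an estimated correlation. Its array means overlapped between genotypes, at 0.15, -0.25, 0.30 and 0.63 in DKO replicates 1 to 4 and -0.24, -0.25, 0.01 and -0.05 in WT, and without DKO replicate 4, the highest, it had adjusted p = 0.0396. Of 29 G2 and mitosis genes 0 passed (0 adjusted over the list alone), with Mki67 at 0.51 ± 0.55. The G2 and mitosis list was higher at camera adjusted p = 0.0171, with adjusted p = 0.625 with an estimated correlation, and had 0.202, 0.113, 0.189 and 0.0634 without WT replicate 1, WT replicate 2, DKO replicate 1 and DKO replicate 4. Of 19 G1 genes the CDK inhibitor gene Cdkn2c rose (0.58 ± 0.15), Ccnd2 (-0.39 ± 0.10) and the inhibitor gene Cdkn2b (-0.41 ± 0.10) fell, and 16 did not pass (1 higher and 3 lower adjusted over the list alone). The G1 list had adjusted p = 0.842, with median and mean above 0 and the test below it. Of 9 lactogen-responsive islet genes Matn2, a matrix protein, rose (0.80 ± 0.19) and 8 did not pass (2 higher adjusted over the list alone), with list adjusted p = 0.465.

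Inflammatory lists were not shifted at 7 months, though single members changed. Of 25 TLR signalling components 1 rose, Lbp, the lipopolysaccharide binding protein (0.86 ± 0.17), and 24 did not pass (1 higher adjusted over the list alone), with list adjusted p = 0.868, a median below 0 and a mean and test above it. Of 24 NF-kappaB inflammatory targets 1 rose, the chemokine gene Cxcl2 (0.46 ± 0.08), and 23 did not pass (1 higher and 1 lower adjusted over the list alone), with list adjusted p = 0.345. Of 22 interferon response genes Usp18 (1.07 ± 0.11) and Ifitm3, a membrane restriction factor (0.64 ± 0.12), rose, Ifih1, a sensor of double-stranded RNA, fell by 0.66 ± 0.09, and 19 did not pass (2 higher and 3 lower adjusted over the list alone), with list adjusted p = 0.351. Of 8 MHC class II genes 0 passed (1 higher adjusted over the list alone), with list adjusted p = 0.102. Of 21 genes in the immediate early and tissue handling genes list Myc, a growth-promoting transcription factor, fell by 1.03 ± 0.23 and 20 did not pass (7 higher and 2 lower adjusted over the list alone). The list was higher at camera adjusted p = 0.0333, with adjusted p = 0.502 with an estimated correlation, and had 0.0816, 0.0673 and 0.231 without WT replicate 3, WT replicate 4 and DKO replicate 3. Of 13 circadian clock genes 0 passed (0 adjusted over the list alone), with camera adjusted p = 0.0176 for a lower list, adjusted p = 0.238 with an estimated correlation, and 0.0552 without DKO replicate 4. The genotypes overlapped in this list, with array means of 0.152, 0.172, -0.071 and -0.088 in WT replicates 1 to 4 and -0.337 to -0.005 in DKO.

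In WT islets, Aldh1a3 rose between 5 weeks and 7 months of diet, and the alpha cell transcription factor genes Irx1 and Irx2 fell. Aldh1a3 rose by 2.14 ± 0.27 (SE; 4.42-fold, limma adjusted p = 0.000598, n = 4 and 4), Slc35f4 by 2.32 ± 0.17 (adjusted p = 7.37e-06) and Gabra4, a GABA receptor subunit, by 1.96 ± 0.24 (adjusted p = 0.000471). Mcoln3, an endolysosomal cation channel, fell by 1.91 ± 0.14 (adjusted p = 7.37e-06) and Pdk4 by 1.63 ± 0.12 (adjusted p = 7.37e-06). In all, 446 genes passed, 255 higher and 191 lower, 93 of them at least 2-fold. Among the 35 named genes past the threshold, 12 had a lower group mean below all array medians, so the sizes of their changes are not exact (Slc35f4, Dock3, Rasl10b, Vstm2a, Srsy, Cmtm5, Chrna3, Sfrp1, Chl1, Pou3f4, Pdgfra and Cdh19).

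Other large rises were P3h2, a collagen prolyl hydroxylase (1.63 ± 0.13), Dock3 (1.61 ± 0.14), Snhg11 (1.56 ± 0.14), Serpina7, a thyroxine carrier (1.52 ± 0.30), Rasl10b (adjusted p = 0.000453), Vstm2a (1.42 ± 0.30) and Cpne4 (1.39 ± 0.17). Other large falls were Srsy (-1.99 ± 0.42), Cmtm5 (-1.86 ± 0.16), the nicotinic receptor gene Chrna3 (-1.84 ± 0.28), Fabp7, a fatty acid binding protein (-1.77 ± 0.19), the sodium channel gene Scn7a (-1.75 ± 0.22), the Wnt inhibitor gene Sfrp1 (-1.72 ± 0.32), the imprinted gene Peg10 (-1.64 ± 0.17) and the adhesion gene Chl1 (-1.64 ± 0.19). Ins2 (0.01 ± 0.07), Gcg (-0.17 ± 0.09), Sst (-0.26 ± 0.08), Mki67 (-0.74 ± 0.55), Ccnd2 (0.05 ± 0.10) and Tlr2 (-0.09 ± 0.10) did not pass. Of 35 named genes past the threshold 27 stayed past it whichever array was left out. The count of 446 became 276 and 244 without WT replicates 1 and 2 at 5 weeks, 221, 256 and 262 without WT replicates 1, 3 and 4 at 7 months, 294 with the acinar score as a covariate and 786 with array weights.

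Of the 30 lists 9 were shifted. Of 6 alpha cell genes Irx1 (-1.22 ± 0.15), Irx2 (-0.88 ± 0.13) and Pou3f4, another transcription factor (-1.11 ± 0.20), fell and 3 did not pass (3 lower adjusted over the list alone). For alpha cell genes camera gave adjusted p = 7.7e-07, and adjusted p = 0.00957 with an estimated correlation. Of 5 delta cell genes 1 fell, Rbp4 (adjusted p = 0.00159), and 4 did not pass (1 higher and 4 lower adjusted over the list alone). For delta cell genes camera gave adjusted p = 0.00186, and adjusted p = 0.0638 with an estimated correlation. Of 3 PP and epsilon cell genes 0 passed (1 lower adjusted over the list alone), with Ghrl at -1.28 ± 0.34. For PP and epsilon cell genes camera gave adjusted p = 0.0111, and adjusted p = 0.428 with an estimated correlation. Of 16 endothelial cell genes 3 rose, the phosphatase gene Ptprb (0.67 ± 0.11), Tek (0.58 ± 0.09) and the fenestral protein gene Plvap (0.71 ± 0.12), and 13 did not pass (5 higher adjusted over the list alone). For endothelial cell genes camera gave adjusted p = 0.00012, and adjusted p = 0.365 with an estimated correlation. Of 29 G2 and mitosis genes 0 passed (0 adjusted over the list alone), with Cep55 at -0.41 ± 0.13 and the cyclin gene Ccnb2 at -0.82 ± 0.34, both of cell division. For G2 and mitosis genes camera gave adjusted p = 3.21e-05 for a lower list, and adjusted p = 0.623 with an estimated correlation. Its array means at 7 months were -0.52, -0.42, 0.05 and 0.06 in WT replicates 1 to 4. Those of replicates 3 and 4 lay within the range at 5 weeks (0.04 to 0.18). Of 26 acinar genes 0 passed (0 adjusted over the list alone). The acinar cell list was lower at camera adjusted p = 8.99e-05, with adjusted p = 0.623 with an estimated correlation and 0.0785 without WT replicate 4 at 7 months.

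Of 15 cholesterol synthesis genes 0 passed (1 lower adjusted over the list alone), with the farnesyl diphosphate synthase gene Fdps at -0.40 ± 0.11. For cholesterol synthesis genes camera gave adjusted p = 0.00329 for a lower list, and adjusted p = 0.623 with an estimated correlation. Of 5 Schwann cell genes 1 fell, the cadherin gene Cdh19 (-1.08 ± 0.26), and 4 did not pass (2 lower adjusted over the list alone). For Schwann cell genes camera gave adjusted p = 0.00417, and adjusted p = 0.108 with an estimated correlation. Of 16 genes in the islet disallowed and dedifferentiation genes list Aldh1a3 rose, Acot7, an acyl-CoA thioesterase, fell by 0.72 ± 0.15 and 14 did not pass (1 higher and 3 lower adjusted over the list alone). That list was lower at camera adjusted p = 0.0219, with adjusted p = 0.622 with an estimated correlation, and had 0.0658 without WT replicate 1 at 5 weeks, and 0.0539 and 0.0593 without WT replicates 1 and 2 at 7 months. Outside the shifted lists, Dcn (-1.38 ± 0.30), Pdgfra (-0.53 ± 0.13), Socs2, a cytokine signalling inhibitor (-1.11 ± 0.21), and Ifih1 (-0.37 ± 0.09) fell, and Rgs5, a pericyte marker (0.40 ± 0.10), and the fatty acid carrier gene Fabp4 (1.05 ± 0.17) rose. Median, mean and test differed in sign for interferon response, T and NK cell, B and plasma cell and adipocyte genes, none of which was shifted.

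In DKO islets, the hormone genes Gcg, Sst, Pyy, Ppy and Ghrl fell between 5 weeks and 7 months. Peg10 fell by 3.50 ± 0.20 (SE; 11.3-fold, limma adjusted p = 4.14e-07, n = 4 and 2), Pdk4 by 2.90 ± 0.15 (adjusted p = 1.23e-07) and Rbp4 by 2.73 ± 0.18 (adjusted p = 1.02e-06). The neuropeptide genes Npy (-2.78 ± 0.25, adjusted p = 1.64e-05) and Vip (-2.59 ± 0.22, adjusted p = 1.21e-05) also fell. Vstm2a rose by 3.47 ± 0.36 (11.1-fold, adjusted p = 6.86e-05), Aldh1a3 by 3.04 ± 0.33 (8.24-fold, adjusted p = 0.000102) and Cd36, a fatty acid transporter, by 2.70 ± 0.36 (adjusted p = 0.000537). In all, 1424 genes passed, 915 higher and 509 lower, 282 of them at least 2-fold. Sizes are not exact for 20 of the 60 named genes past the threshold, with a lower group mean below all array medians: Vstm2a (2.99 at 5 weeks), Peg10, Pdk4, Npy, Vip, Cd36, Clmp, Cck, Slc35f4, Bcat1, Msln, Ndst4, Ppp1r17, Fabp7, Irx1, Pou3f4, Lepr, Adgre1, Itgam and Mrc1.

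Other large rises were Clmp (2.81 ± 0.39), Serpina7 (2.56 ± 0.36), Cck (2.53 ± 0.67), Lin7a (2.35 ± 0.35), Slc35f4 (2.25 ± 0.20), Bcat1 (2.25 ± 0.35) and Zcchc12 (2.05 ± 0.34). Cck in replicate 2 at 7 months (2.96) was near the mean at 5 weeks (2.88), with 6.01 to 6.54 in the other 7-month arrays. Other large falls were Msln (-3.43 ± 0.30), the heparan sulfate enzyme gene Ndst4 (-2.89 ± 0.24), Kcnip3, a calcium-binding channel partner (-2.68 ± 0.33), Ppp1r17 (-2.46 ± 0.30) and Fabp7 (-2.39 ± 0.23). The signal of the Tlr2 probe set rose by 0.51 ± 0.12, while Ins2 (0.03 ± 0.09), Mki67 (0.02 ± 0.67) and Ccnd2 (-0.32 ± 0.13) did not pass. As it is not given whether the Tlr2 probe set lies in the deleted part, its rise does not show an intact Tlr2 transcript in DKO islets. Of 60 named genes past the threshold 33 stayed past it whichever array was left out, and 26 did not pass without DKO replicate 1 at 5 weeks. The count of 1424 became 378 without that array, 938 without DKO replicate 3 at 7 months, 347 with only the arrays compared and 931 with the acinar score as a covariate, and centring each array on its median gave 1283 higher and 402 lower.

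Of the 30 lists 8 were shifted. Of 6 alpha cell genes 4 fell, Gcg (-0.77 ± 0.11), Irx1 (-1.57 ± 0.18), Irx2 (-1.76 ± 0.16) and Pou3f4 (-1.42 ± 0.25), and 2 did not pass (1 higher and 4 lower adjusted over the list alone). For alpha cell genes camera gave adjusted p = 1.28e-05, and adjusted p = 0.0253 with an estimated correlation. Of 5 delta cell genes 3 fell, Sst (-1.07 ± 0.10), Rbp4 and the ghrelin receptor gene Ghsr (-0.90 ± 0.18), Lepr rose (0.76 ± 0.21) and 1 did not pass (1 higher and 3 lower adjusted over the list alone). For delta cell genes camera gave adjusted p = 0.000185, and adjusted p = 0.0253 with an estimated correlation. All 3 PP and epsilon cell genes fell (3 lower adjusted over the list alone), Pyy by 1.63 ± 0.14, Ppy by 1.23 ± 0.20 and Ghrl by 2.13 ± 0.42. For PP and epsilon cell genes camera gave adjusted p = 5.63e-06, and adjusted p = 0.0626 with an estimated correlation. Of 16 endothelial cell genes 5 rose and 11 did not pass (11 higher adjusted over the list alone), including Tek (0.96 ± 0.11), Ptprb (0.95 ± 0.13), Plvap (0.96 ± 0.15) and the cadherin gene Cdh5 (0.58 ± 0.14). For endothelial cell genes camera gave adjusted p = 5.63e-06, and adjusted p = 0.176 with an estimated correlation. Of 15 stellate cell, pericyte and fibroblast genes 4 rose, Acta2 (1.72 ± 0.17), Rgs5 (0.77 ± 0.12), the calcification inhibitor gene Mgp (1.30 ± 0.21) and Pdgfrb, a pericyte receptor (0.98 ± 0.19), and 11 did not pass (5 higher adjusted over the list alone). For stellate cell, pericyte and fibroblast genes camera gave adjusted p = 1.28e-05, and adjusted p = 0.326 with an estimated correlation.

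Of 21 unfolded protein response genes Sel1l (0.56 ± 0.12), Dnajc3 (0.63 ± 0.16) and Edem1 (0.53 ± 0.14) rose and 18 did not pass (3 higher adjusted over the list alone). The unfolded protein response list had camera adjusted p = 0.0107, adjusted p = 0.745 with an estimated correlation, and 0.495 without DKO replicate 1 at 5 weeks. Of 21 genes in the immediate early and tissue handling genes list Zfp36 (0.83 ± 0.14), the phosphatase gene Dusp1 (0.60 ± 0.13) and the antiproliferative gene Btg2 (0.61 ± 0.16) rose and 18 did not pass (5 higher adjusted over the list alone). It had camera adjusted p = 0.0339, adjusted p = 0.745 with an estimated correlation, 0.119 without DKO replicate 2 at 5 weeks and 0.106 without DKO replicate 3 at 7 months. Of 26 acinar genes 0 passed (0 adjusted over the list alone), and the acinar cell list was lower at camera adjusted p = 0.00578, with adjusted p = 0.745 with an estimated correlation and 0.0624 without DKO replicate 1 at 5 weeks. In lists that were not shifted, the macrophage genes Adgre1 (0.98 ± 0.17), Itgam (0.88 ± 0.18), Lyz2 (1.07 ± 0.25) and Mrc1 (0.72 ± 0.18) rose, as did the carnitine carrier gene Slc25a20 (0.83 ± 0.15), the peroxisomal enzyme gene Ehhadh (0.55 ± 0.15), Fabp4 (1.31 ± 0.21), the growth hormone receptor gene Ghr (0.42 ± 0.11) and Tnfrsf11b, a decoy receptor (1.47 ± 0.32). Socs2 (-0.96 ± 0.26) and Tspan8 (-1.35 ± 0.26) fell. Of 22 interferon response genes Usp18 rose (0.81 ± 0.13), Ifih1 (adjusted p = 0.000102) and the transcription factor genes Irf7 (-0.92 ± 0.23) and Irf9 (-0.61 ± 0.16) fell and 18 did not pass (2 higher and 4 lower adjusted over the list alone), with list adjusted p = 0.0743. Median, mean and test differed in sign for G1, duct and sex-linked genes, none of which was shifted.

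Whether the genotype difference itself changed between the times was tested by the interaction. Genotype differences were more negative at 7 months for Rbp4 (-1.73 ± 0.23, SE; limma adjusted p = 0.0172), Pyy (-1.41 ± 0.19, adjusted p = 0.0172), Adgrv1, an adhesion receptor (-1.05 ± 0.14, adjusted p = 0.0172), and Sst (-0.82 ± 0.13, adjusted p = 0.026). They were more positive for Clmp (3.24 ± 0.50, adjusted p = 0.0197), the phospholipid-binding protein gene Anxa1 (1.83 ± 0.27, adjusted p = 0.0177) and the galanin receptor gene Galr1 (0.81 ± 0.12, adjusted p = 0.0177). In all, 17 genes passed, 5 higher and 12 lower, 13 of them at least 2-fold. For 8 of the 16 named genes past the threshold (Clmp, Anxa1, Ppargc1a, Peg10, Ust, Ffar4, Pdk4 and Adgrv1) the lowest group mean lay below all array medians, and the sizes are not exact. The others named were Ppargc1a (-2.52 ± 0.40), Peg10 (-1.86 ± 0.26), Ust (-1.43 ± 0.22), Clip4 (-1.38 ± 0.23), the fatty acid receptor gene Ffar4 (-1.32 ± 0.21), Pdk4 (-1.27 ± 0.19), Cdh8 (-1.17 ± 0.18), Glt1d1 (1.23 ± 0.19) and the metalloreductase gene Steap4 (0.97 ± 0.14). Gcg (-0.60 ± 0.14), Tlr2 (0.60 ± 0.16), Ins2 (0.02 ± 0.11), Mki67 (0.76 ± 0.86) and Ccnd2 (-0.36 ± 0.16) did not pass. Of 16 named genes past the threshold 0 stayed past it whichever array was left out, and 15 did not pass without DKO replicate 1 at 5 weeks. The count of 17 became 2 without that array, 36 without DKO replicate 2 and 8 without WT replicate 3 at 5 weeks, and 10, 27 and 185 without WT replicate 2, DKO replicate 1 and DKO replicate 2 at 7 months. It was 0 over all probe sets, 46 with a trended robust prior, 35 without dim genes and 28 with array weights, and centring gave 14 higher and 10 lower against 5 and 12.

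Of the 30 lists 7 were shifted in the interaction. Of 15 stellate cell, pericyte and fibroblast genes 0 passed (11 higher adjusted over the list alone), with Dcn at 1.83 ± 0.48 and Acta2 at 1.20 ± 0.22. For stellate cell, pericyte and fibroblast genes camera gave adjusted p = 1.48e-11, and adjusted p = 0.13 with an estimated correlation. Of 3 PP and epsilon cell genes 1 passed, Pyy (2 lower adjusted over the list alone), with Ppy at -0.96 ± 0.26. For PP and epsilon cell genes camera gave adjusted p = 0.000132, and adjusted p = 0.13 with an estimated correlation. Of 5 delta cell genes Sst and Rbp4 passed and 3 did not (3 lower adjusted over the list alone). For delta cell genes camera gave adjusted p = 0.00474, and adjusted p = 0.13 with an estimated correlation. The immediate early and tissue handling genes (0 of 21 passed, 2 higher adjusted over the list alone, Zfp36 at 0.89 ± 0.18) and the islet disallowed and dedifferentiation genes (0 of 16, 1 higher adjusted over the list alone) had camera adjusted p = 0.000212 and 0.00345, with adjusted p = 0.297 for both with an estimated correlation. Of 16 endothelial cell genes 0 passed (1 higher adjusted over the list alone). For endothelial cell genes camera gave adjusted p = 0.0227, and adjusted p = 0.761 with an estimated correlation. The endothelial cell list had 0.0734 without WT replicate 1 and 0.503 without DKO replicate 1 at 5 weeks, and 0.0568 without WT replicate 2 and 0.137 without DKO replicate 4 at 7 months. Of 11 B and plasma cell genes 0 passed (0 adjusted over the list alone). For B and plasma cell genes camera gave adjusted p = 0.0212, adjusted p = 0.809 with an estimated correlation, 0.186 without DKO replicate 2 at 5 weeks and 0.527 without DKO replicate 4 at 7 months. The count of shifted lists was 13 without DKO replicate 2 at 7 months. Median, mean and test differed in sign for TLR signalling, G1, cholesterol, duct and Schwann cell genes, none of which was shifted.

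Genes that passed at both times were counted for the genotype comparisons, which share no arrays but come from a model with a single variance per gene, so that steady genes tend to pass at both. Of the 187 genes past the threshold at 5 weeks and the 887 at 7 months, 99 passed at both, where 8.81 would be shared by independent lists, 48 higher and 51 lower both times and 0 in opposite directions. They include Tlr2, Fbp1, Reg2, Aldh1a3, Trnp1, Ust, Npas4 and Dock10. Across genes, which are not independent replicates, the log2 differences at the 2 times had Pearson's r = 0.37. Over time, 253 genes passed in both WT and DKO islets, where 33.8 would be shared by independent lists, 139 higher and 114 lower in both and 0 in opposite directions, with r = 0.533 across genes. They include Aldh1a3, Slc35f4, Peg10, Pdk4, Irx1, Irx2, Tek and Ptprb.

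**Figure D4:**
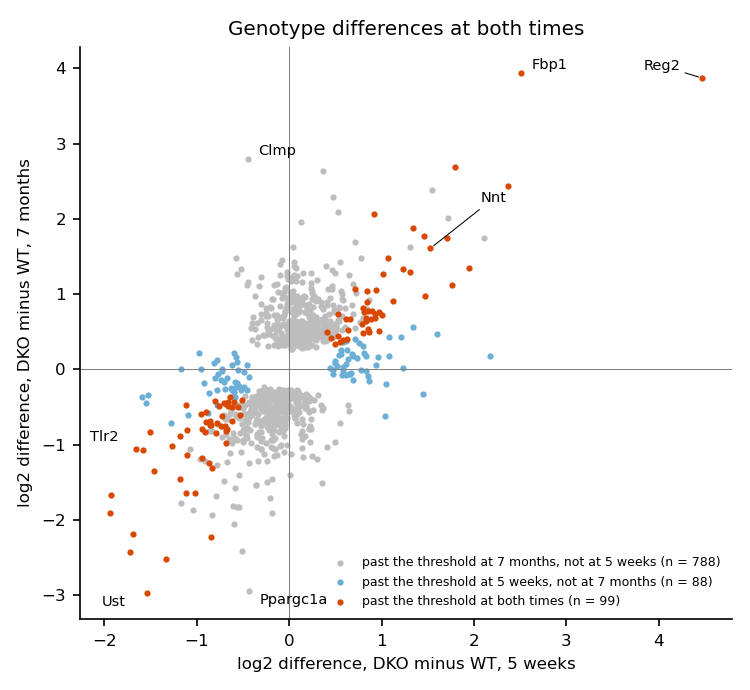
Log2 difference between DKO and WT islets at 5 weeks (horizontal axis) and 7 months (vertical axis) for each gene past the threshold at either time (points), coloured by the time at which it passed. The 99 genes that passed at both times fell at both (51 genes, lower left) or rose at both (48 genes, upper right).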

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

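Of the tests in this part, the counts of genes near the targeted loci and the splits of arrays were written down before the results were seen, and the others were chosen only after. In 435 groups of 4 arrays for named genes, 26 had an array far from the other 3 by Dixon's test of the gap to the nearest array over the range, and in 90 groups of list means 6 did. Chance flags about 1 in 20 groups, so the count for genes is near what chance gives. DKO replicate 4 at 7 months held 4 of the flags for genes and 2 of those for list means. It was not the array with the most, as WT replicate 2 at 5 weeks and DKO replicate 2 at 7 months held more flags for genes.

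In WT at 5 weeks, replicate 4 lay apart for Bcat1 (2.33, others 3.02 to 3.08) and Cdkn2c (4.85, others 4.42 to 4.43), and replicate 3 for Fam163a (5.48, others 4.28 to 4.40). Replicate 2 lay apart for Gabra4 (3.85, others 5.00 to 5.06), Gp2 (3.40, others 5.07 to 5.41), Myc (5.79, others 6.45 to 6.51), Ppargc1a (6.00, others 6.30 to 6.32) and Prss3 (2.39, others 3.99 to 4.22). The same array lay apart in the list means of acinar cells (-1.50, others 0.34 to 0.58), duct cells (-0.03, others at 0.03) and the unfolded protein response (-0.29, others -0.18 to -0.16). In WT at 7 months, replicate 1 lay apart for Gabra4 (6.73, others 6.67 to 6.68), Itih1 (2.78, others 3.66 to 3.73) and Vstm2a (6.04, others 4.54 to 4.70), replicate 2 for Ctrc (5.29, others 3.28 to 3.46), Cyp39a1 (4.46, others 4.54 to 4.55) and Kcnip3 (5.94, others 4.93 to 5.04), and replicate 3 for Depp1 (8.71, others 8.96 or more).

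In DKO at 7 months, replicate 2 lay apart for Cck (2.96, others 6.01 to 6.54), Rasl10b (5.06, others 5.67 to 5.72), Reg3b (5.53, others 3.64 to 3.94), Sel1l (9.25, others 9.53 to 9.57), Vstm2a (5.88, others 6.61 to 6.73) and Vwf (4.12, others 4.66 to 4.74), and in the list mean of the unfolded protein response (-0.03, others 0.33 to 0.40). Replicate 1 lay apart for Pou3f4 (4.06, others 3.24 to 3.30). Replicate 4 lay apart for Dock10 (5.83, others 4.91 to 4.98), Dock3 (5.47, others 5.15 to 5.17), Lyz2 (7.76, others 6.52 to 6.66) and Plvap (9.45, others 9.26 to 9.28), and in the list means of T and NK cells (1.25, others -0.05 to -0.01) and B and plasma cells (1.18, others -0.12 to 0.02).

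These genes passed the interaction test, though 0 of them stayed past the threshold with each array left out, 15 were lost without DKO replicate 1 at 5 weeks and 0 passed over all probe sets. They are given as interaction (5 weeks, 7 months): Clmp 3.24 (-0.45, 2.79), Anxa1 1.83 (-0.56, 1.27), Glt1d1 1.23 (-1.59, -0.36), Steap4 0.97 (-0.35, 0.62), Galr1 0.81 (-0.05, 0.76), Ppargc1a -2.52 (-0.43, -2.95), Peg10 -1.86 (0.36, -1.50), Rbp4 -1.73 (-0.18, -1.91) and Ust -1.43 (-1.54, -2.97). The rest were Pyy -1.41 (0.01, -1.40), Clip4 -1.38 (-0.85, -2.23), Ffar4 -1.32 (0.15, -1.17), Pdk4 -1.27 (-0.19, -1.46), Cdh8 -1.17 (-0.36, -1.53), Adgrv1 -1.05 (-0.05, -1.10) and Sst -0.82 (-0.06, -0.88). It also shifted the lists of immediate early genes (camera adjusted p = 0.000212), disallowed genes (0.00345), delta cells (0.00474), PP and epsilon cells (0.000132), endothelial cells (0.0227), stellate cells, pericytes and fibroblasts (1.48e-11) and B and plasma cells (0.0212). With an estimated correlation 0 of these lists kept the call, with adjusted p of 0.297, 0.297, 0.13, 0.13, 0.761, 0.13 and 0.809 in that order.

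The alpha, delta and PP and epsilon cell genes (14 genes, 8 of them past the threshold, mean -0.65 ± 0.07 in DKO islets at 7 months) could come from dilution by RNA of non-endocrine cells or from carried-over acinar RNA. Such dilution would lower beta cell genes as much, but those fell less (-0.19). The difference per array was -0.46 ± 0.07 (exact permutation p = 0.0286, the lowest that 4 against 4 arrays allow). The beta cell list holds Ins2, whose probe set may not show a change, and the list mean in DKO replicate 2 lay above all WT arrays. The values argue against dilution as the only source, as far as the beta cell probe sets can show a fall. With the acinar score as a covariate the mean of the alpha, delta and PP and epsilon cell genes stayed at -0.69 ± 0.07, which argues against acinar RNA. A larger share of beta cells, fewer of these cells and lower transcripts in each cell were not tested and are left open.

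Genes that changed with genotype at both times could come from the genetic background rather than the missing receptors. Within 10 Mb of Tlr2 or Tlr4 lay 3 of 98 such genes (Akna, Ctnnal1 and Snord73b, looked up after the values were seen; one-sided Fisher's exact test, p = 0.193), but at 5 weeks alone 7 of 186 did (p = 0.0257) and at 7 months 18 of 885 (p = 0.142), so carried-along neighbours are left open for part of the genes, and 51 of the 98 had another within 5 Mb, against a median of 40 and at most 63 in 10000 random draws (share as high 0.0342). The rise of Nnt (at the brighter of its 2 probe sets), which C57BL/6J mice carry as a deletion and other C57BL/6 substrains do not, prompted a test of 8 other genes recalled as varying among C57BL/6 colonies: of the 6 measured, Ide (-0.78 and -0.71), Wdfy1 (0.98 and 0.76) and Entpd4 (-0.74 and -0.75) changed at both times and Crb1, Cyfip2 and Mmrn1 did not (one-sided Fisher's exact test, p = 2.79e-06). A shorter list of 4 of these, settled after the values were seen, gave p = 1.41e-07 by the same exact test, and as both tests were written after the values were seen neither p is relied on. Whether WT and DKO mice were of different C57BL/6 substrains, which the labels do not give, is left open, and part of the genotype difference could be of that origin.

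The immune and connective tissue lists that camera called higher in DKO islets at 7 months could come from other tissue in DKO replicate 4. Without it the T and NK cell list had adjusted p = 0.656 and the B and plasma cell list 0.593, and the macrophage list 0.0634 from 0.00116. As that array stood apart before it was left out, this does not show where the signal came from, and the macrophage means of the other 3 DKO arrays were -0.03, 0.19 and 0.08 against -0.10 to -0.01 in WT. The stellate cell, pericyte and fibroblast list stayed at 4.45e-09 from 6.51e-10. Its mean was 0.63 ± 0.15 with the acinar score as a covariate against 0.70 ± 0.13 without. These values argue against other tissue in DKO replicate 4 alone, or acinar RNA, as the only source. Other tissue carried over in all the DKO arrays was not tested and is left open. Their means for this list were 0.185, 0.291, 0.388 and 0.835, against -0.352 to -0.16 in WT. With an estimated correlation the stellate cell list had adjusted p = 0.118, the macrophage list 0.439 and the T and NK cell and B and plasma cell lists 0.536, so all these calls rest on the preset correlation.

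The 8 arrays can be split into 4 and 4 in 35 ways. The real split gave the most changed genes for genotype at 7 months (887, highest other 96) and for time in WT (446, highest other 14). In each case the share of splits with as large a count was 0.0286, the lowest that 35 splits allow. The other splits mix the groups, which adds the group difference to the spread, so low counts there are partly built in. Chance is thus less likely for the gene counts but not excluded. For shifted lists, with the real split included, 2 splits gave as many for genotype (18, highest other 19) and 4 for time in WT (9, highest other 9). The mixed splits gave 3 to 19 shifted lists for genotype at 7 months and 0 to 9 for time in WT. Chance therefore cannot be excluded for the list counts.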

How the results depend on the processing

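Of 243 named results 194 were past the threshold. Of these, 122 stayed past it under every alternative that kept all arrays, 115 stayed with each array left out in turn, and 0 changed sign under any alternative. A result whose gene was left out by an alternative, as happened without dim genes, was not counted as lost under it. Where counts moved by more than 1.5 times, the cause was not tested unless fewer arrays show it.

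Genes for genotype at 5 weeks numbered 187, and 120 with only the arrays compared, 282 with the trended robust prior, 98 with the acinar score and 44 to 236 with an array left out. At 7 months they numbered 887, and 488 with only the arrays compared, 586 with the acinar score and 528 to 1681 with an array left out. For time in WT the count was 446, and 294 with the acinar score, 786 with array weights and 221 to 527 with an array left out. For time in DKO it was 1424, and 347 with only the arrays compared, 931 with the acinar score and 378 to 2051 with an array left out. The interaction had 17 genes, and 46 with the trended robust prior, 35 without dim genes, 0 over all probe sets, 28 with array weights and 2 to 185 with an array left out. Centring arrays on their medians gave 674 higher and 294 lower genes for genotype at 7 months against 460 and 427, 1283 and 402 for time in DKO against 915 and 509, and 14 and 10 in the interaction against 5 and 12, where quantile normalization gave 9 and 12.

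Shifted lists for genotype at 5 weeks numbered 6 (3 without dim genes, 4 to 8 with an array left out), at 7 months 18 (10 to 19), for time in WT 9 (8 to 11), for time in DKO 8 (8 to 14) and in the interaction 7 (5 to 13). With an estimated correlation these were 0, 0, 1, 2 and 0. The preset correlation of 0.01 thus carries most of the list calls.

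The replicate numbers do not pair the samples. With the replicate block the gene counts were 121 for genotype at 5 weeks, 864 for time in DKO and 10 in the interaction, and the others stayed within 1.5 times. The deviations of each array from its group means were also correlated across genes between arrays of different groups. For arrays of the same number the correlation was -0.163 to 0.158 (18 pairs, median -0.009). For those of other numbers it was -0.148 to 0.191 (54 pairs, median 0.004). No background level was measured here, so the limit that signal over background sets for dim genes such as Tlr4 is not known.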

Other observations

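Nnt, noted here after its values were seen, rose in DKO islets by 1.53 at 5 weeks and 1.61 at 7 months at its brighter probe set. Its other, dimmer probe set averaged 4.45 in DKO and 4.15 in WT islets at 5 weeks, and 4.43 and 4.24 at 7 months, with overlapping arrays. The first principal component of the arrays held 31.9% of the variance and the next 14.4%.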
